A study of Mus musculus with 2 samples.

How the data were processed

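Single cells from tumors grown in wild-type (WT) mice and in mice carrying the S303/7A mutations of heat shock factor 1, in which serines of the protein are replaced by alanine, were profiled as 1 library per genotype. Per the labels' protocols, tumors were digested with enzymes, live CD45-positive and CD45-negative cells were sorted, and the sorted fractions were mixed 5 to 1 before 3′ end droplet libraries (10x Genomics, version 2 chemistry) were made. The series' design text speaks of tumors from 4 mice being pooled, so the animals within a library cannot be told apart and there are no replicates.

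The deposited expression values are natural log values: the natural log of 1 plus a cell's UMI count for a gene, scaled to 100000 UMIs per cell by the authors and rounded to 3 decimals. A UMI (unique molecular identifier) marks 1 captured RNA molecule. The total UMI count and the number of detected genes of each cell were deposited as whole counts, and the mitochondrial share of each cell was deposited as a percent. The deposited annotation also gives each cell's library, 1 of 22 clusters, 1 of 11 cell classes and 1 of 3 copy number groups, and the methods behind these are not given in the sources used here. Cell Ranger and Seurat 3.0, and the mouse genome builds mm10 and GRCm38, are named per the submitters' processing notes, while the filters on cells and genes are not given in the sources used here. The table holds 11456 cells and 16416 genes, the shallowest cell has 538 UMIs, and the highest mitochondrial share is 9.98%.

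Undoing the log and multiplying by the cell's total gave whole UMI counts: 99.9% of nonzero values lay within 0.1 UMI of a whole number. The recovered numbers of detected genes matched the deposited numbers in 11456 cells, and recovered totals differed from deposited totals by at most 3 UMIs in any cell. Expression in a class was measured as the mean over its cells of UMIs per 10000 (CP10K), and as the sum of UMIs. Differences are given as the log2 ratio of S303/7A over WT with a pseudocount of 0.1 CP10K, which understates the difference of low genes, and as the ratio of summed UMIs relative to all UMIs of the class, with an exact (Clopper-Pearson, conditional) 95% interval. Shares of cells carry exact (Clopper-Pearson) 95% binomial intervals. All intervals cover counting error only, since cells are not replicates, and no p-value was made from cells.

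The deposited classes were used as the main classes, and 8 of them with at least 50 cells in each library were compared. Shares are given within CD45-positive classes and within CD45-negative classes, because the sort and the mix set the balance between them. Marker and program genes, 31 gene lists, the rule for named genes and most of the other settings tried were fixed before the data were examined. Named genes are the 12 highest and 12 lowest log2 ratios in NK cells, and the 5 highest and 5 lowest in each other class, among genes found in at least 10% of the class's cells in 1 library. That rule leaves out mitochondrially encoded genes, ribosomal protein genes, gene models named Gm or Rik, and V, D and J segments of antigen receptors. Other clone-named genes and receptor constant genes stay in. It also names any list member in NK cells, the 4 list members with the largest absolute log2 ratio in each other class, Hsf1 in every class, and the markers and leading genes of clusters. For each list, the median log2 ratio was taken over members with at least 0.1 CP10K in 1 library, and placed as a percentile among 10000 random lists of the same size matched on mean expression in 20 bins. Percentiles describe these 2 libraries and not the genotypes. No list median was tested. Some choices were made after values had been seen: which list medians are treated as leading results, the limit of lineage lists to their own classes when alternatives were run, the split of tumor cells by cluster, the doublet cut given below, and 4 further settings (thinned cells for lists, clusters weighted equally, lists without doublets, and shares without cluster C09). The lineage limit and the tumor split followed a first run of the alternatives over all pairs of list and class.

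Cells were also thinned to 1000 UMIs each, which left out 199 WT and 63 S303/7A cells with fewer. Doublets were scored with Scrublet as implemented in scanpy 1.11.5. Its automatic threshold marked 0.932% of WT and 0.167% of S303/7A cells, so as an alternative the highest-scoring cells, 360 in WT and 215 in S303/7A, were left out, which is the expected rate of 5.32% and 3.84% plus ties at the cut. No cell was left out of the main values. Another set of clusters was made with the Leiden method (leidenalg 0.10.2, resolution 1, 2000 variable genes, 30 principal components, 20 neighbours) and named by the fixed markers. Gene positions come from GENCODE release M21 on GRCm38. The scripts ran on Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.

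The measure and its interval were tested on simulated data: NK counts were drawn at the real depths from 1 common profile with 50 genes shifted at each of 4 known folds, among 4647 genes found in at least 10% of NK cells. Simulated cells of a library differed only in depth and counting error, so the test leaves out variation between real cells. Coverage in real classes may be lower. Over the unshifted genes, 95.5% of intervals covered the truth. The intervals covered it for 96% of genes at a fold of 0.25, 98% at 0.5, 94% at 2 and 96% at 4, and the direction was right for 100% at each size. With the pseudocount, the median log2 ratio of genes truly lower by 2 log2 units was −1.53, and of genes truly higher by 2 it was 1.83.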

Results

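The tumors of mice with S303/7A heat shock factor 1 (HSF1), the transcription factor that switches on chaperone genes under protein stress, were set beside tumors of WT mice by single-cell RNA sequencing. The series' title places the question in natural killer (NK) cells and asks how their stress response state bears on immunity against tumors. There was 1 library per genotype, each made from pooled mice, so no difference below has a replicate check and every interval covers counting error only. The WT library held 6654 cells and 87075636 UMIs, and the S303/7A library 4802 cells and 72802161 UMIs. The median cell had 7698 UMIs and 2165 genes in WT, and 13028 UMIs and 2989 genes in S303/7A. After thinning to 1000 UMIs the medians were 551 and 548 genes.

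Expression ratios below are relative to all UMIs of a cell or class. A lower value is thus a smaller share of UMIs and need not mean fewer UMIs per cell. The depth gap between the libraries differed by class. The ratio of median UMIs per cell, S303/7A over WT, was 2.61 in macrophages (MF), 2.10 in monocytes (Mo), 1.83 in regulatory T cells (Treg), 1.78 in dendritic cells (DC), 1.62 in NK cells and 1.32 in CD8 T cells (CD8T), and 1.1 in both the Tumor and the Stromal class. The names are the authors' deposited classes, and leading genes of several clusters fit them: Ncr1, Klrb1c and Gzma in the NK cluster C10, Foxp3 and Il2ra in the Treg cluster C12, C1qc and Ms4a7 in the MF cluster C03, Chil3 and Plac8 in the Mo cluster C07. The MF cluster C02 was led by Ly6i and class II genes and had no macrophage marker among its 10 leading genes. The DC class joined clusters led by Cd209a (C16), Ccr7 (C17) and Xcr1 (C20). The class deposited as Gr joined a neutrophil cluster led by S100a8 and S100a9 (C18) and a mast cell cluster led by Cma1 and Mcpt4 (C22).

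Among CD45-positive cells, NK cells and monocytes took smaller shares in the S303/7A library, and macrophages a larger one. NK cells made up 8.58% (95% interval 7.75 to 9.48) of 4159 cells in WT and 5.20% (4.51 to 5.96) of 3729 cells in S303/7A, a ratio of 0.606 (0.506 to 0.724). Monocytes made up 12.5% (11.5 to 13.5) and 7.16% (6.35 to 8.04), and macrophages 47.7% (46.2 to 49.2) and 55.8% (54.2 to 57.4). B cells were at 1.13% (0.831 to 1.5) in WT and 0.375% (0.205 to 0.629) in S303/7A, from 47 and 14 cells. CD8 T cells were at 16.7% and 16.5%, a ratio of 0.993 (0.889 to 1.11), and Treg at 6.13% and 5.90%, a ratio of 0.962 (0.800 to 1.16). DC were at 5.39% and 6.36%, plasmacytoid DC at 0.793% and 0.858%, and Gr at 1.15% and 1.77%, a ratio of 1.53 (1.04 to 2.27). Clusters made here drew the border between monocytes and macrophages elsewhere, and the share ratio was then 1.87 for MF and 0.171 for Mo. Without the shallowest 10% of cells of each library no B cell of S303/7A remained.

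**Figure D1:**
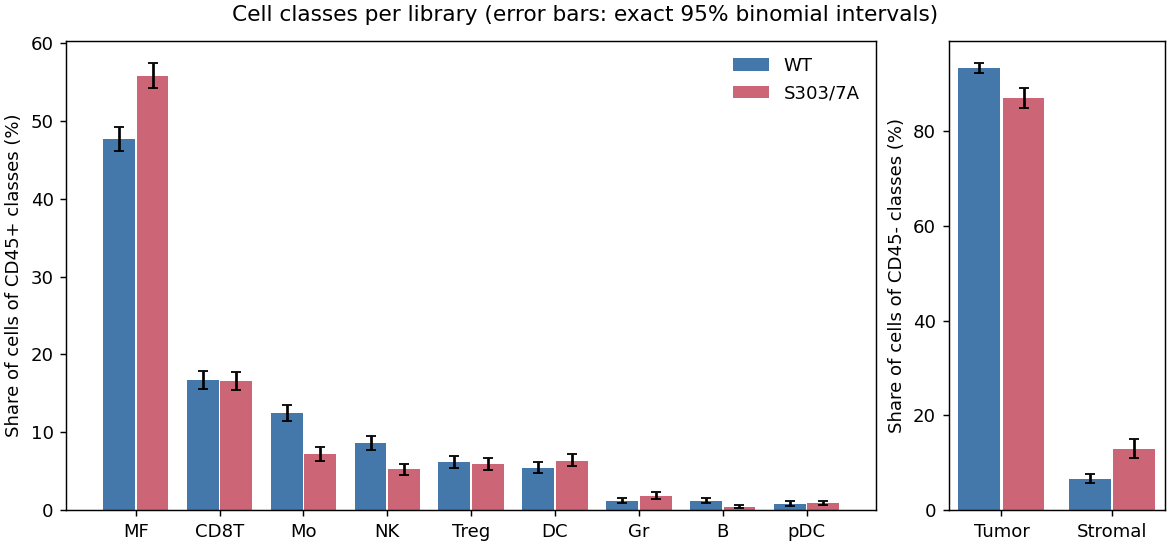
Share of cells (%) of each class among CD45-positive classes (left) and among CD45-negative classes (right), for WT (blue) and S303/7A (red), with exact 95% binomial intervals that cover counting error only. NK cells were at 8.58% in WT and 5.20% in S303/7A, and macrophages at 47.7% and 55.8%.

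Among CD45-negative cells, the Stromal class made up 6.53% (5.59 to 7.57) in WT and 12.9% (10.9 to 15) in S303/7A, a ratio of 1.97 (1.56 to 2.48), and tumor cells the rest. The Stromal ratio was 1.20 without the shallowest 10% of cells and 1.17 with all cells as the denominator. Cells of CD45-negative classes were 37.5% of the WT library and 22.3% of the S303/7A library, against 16.7% in the stated mix, so shares of all cells follow the mix as well as the tumor. Within the Tumor class the cycling cluster C04, with Ube2c at 2.89 CP10K in WT, held 33.4% of WT and 14.2% of S303/7A tumor cells, and C08, led by Spp1 and Dmp1, held 16.8% and 29.8%. Within CD8T, the cycling cluster C11, led by Hist1h2ap and Pclaf, held 44.2% and 28.5%. Within MF, C02, led by Ly6i and class II genes, held 35.4% and 25.3%.

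Hsf1 itself was a low transcript in every class, and the chaperone genes that HSF1 drives were modestly lower in S303/7A in most classes. In NK cells Hsf1 (chromosome 15, 76477422 to 76501913, GRCm38) was at 0.219 CP10K in WT and 0.133 in S303/7A, a UMI ratio of 0.70 (0.351 to 1.35) on 26 and 16 UMIs. It was at 0.144 and 0.0973 CP10K in MF, a UMI ratio of 0.758 (0.624 to 0.923). Since the mutation changes 2 amino acids and need not alter the RNA level, Hsf1 RNA does not check the labels. Of the heat shock response genes, 18 of 22 measured were lower in S303/7A NK cells, with a median log2 ratio of −0.22 at percentile 0.44 of random lists. The counts were 17 of 22 in CD8T (−0.27, percentile 0), 21 of 22 in Treg (−0.28, 0.42), 20 of 23 in MF (−0.18, 0.03; −0.02 in its largest WT cluster, C02, percentile 36.3), 15 of 22 in Mo (−0.12, 4.11; −0.36 in thinned cells) and 16 of 21 in DC (−0.22, 0.26). In the Stromal class 11 of 25 were lower, at 0.06 and percentile 63.8. In the Tumor class 21 of 23 were lower (−0.29, percentile 0), with −0.04 in its cluster C14 (percentile 60.9). The lower values were thus not particular to immune cells, and the Tumor class had the lowest median of the classes compared. They do not show that the mutation acts within the cells where they were seen.

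Among single chaperones, Hspa1a, the inducible HSP70, was far lower in S303/7A myeloid cells. It was at 1.85 and 0.505 CP10K in Mo, a UMI ratio of 0.196 (0.154 to 0.247), at 1.17 and 0.213 in DC (0.291, 0.228 to 0.37), and at 0.737 and 0.24 in MF (0.26, 0.232 to 0.29). Its neighbour Hspa1b was at 0.125 and 0.0298 CP10K in MF; reads of this near-identical pair can be split between the copies by the counting. In NK cells Hsp90ab1 was at 12.9 and 10.8 CP10K, a UMI ratio of 0.879 (0.82 to 0.941), Ubb at 27.3 and 22.3 (0.846, 0.803 to 0.89), and Hspe1 at 3.06 and 3.64 (1.17, 1.02 to 1.33). Hspa1a in Treg went the other way in the mean, 0.396 and 1.03 CP10K, with a UMI ratio of 1.19 (0.693 to 2.09). Genes of the immediate early response to dissociation were lower in NK cells (−0.32, percentile 0.14), CD8T (−0.21, 0.39), Treg (−0.54, 0), Mo (−0.32, 0.27), DC (−0.19, 1.09) and Stromal cells (−0.63, 0.145). They were at −0.15 in MF, which was 0.02 with clusters weighted equally, with 0.17 in C03 (percentile 98.6), and at −0.06 in tumor cells (45.8). The tumor clusters ranged from −0.23 in C04 (11 of 14 lower, percentile 0.01) to 0.03 in C14 (81.2). Single members differed: Fos was at 2.22 and 1.39 CP10K in Treg and at 1.17 and 1.39 in NK cells.

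In NK cells of the S303/7A library, transcripts of cytotoxic effectors and of several surface receptors took a smaller share of UMIs. Maturation genes were mixed. Median depth was 1.62 times that of WT, so a smaller share need not mean fewer transcripts per cell. Of the NK cytotoxic effector genes, 14 of 19 measured were lower, at a median log2 ratio of −0.31 and percentile 0. Gzmb, the granzyme that starts caspase cleavage in target cells, was at 40.5 CP10K in WT and 23.6 in S303/7A, a UMI ratio of 0.596 (0.568 to 0.626), and Gzma was at 70.2 and 41.5 (0.544, 0.523 to 0.567). Prf1, the pore-forming perforin, was at 5.40 and 4.80 (0.85, 0.758 to 0.953), and Ccl4 at 15.8 and 11.2 (0.546, 0.503 to 0.591). Ifng was at 1.27 and 0.944 (0.669, 0.515 to 0.864). Lamp1 and Xcl1 were higher, Xcl1 at 12.6 and 14.1 CP10K (1.08, 1.02 to 1.16). Gzmf, at 3.92 and 0.272 CP10K, was found in 4.2% and 2.06% of NK cells, so its mean rests on few cells.

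Of the genes for activating receptors, 11 of 19 were lower (median −0.12, percentile 6.87). Klrb1c, which encodes NK1.1, was at 6.22 and 3.86 CP10K (UMI ratio 0.607, 0.536 to 0.686) and Cd7 at 5.66 and 3.16 (0.51, 0.447 to 0.581), against Ncr1 at 4.2 and 4.79 (1.1, 0.975 to 1.24) and Klra4 at 4.72 and 6.34 (1.29, 1.16 to 1.45). Of the inhibitory receptor genes, 9 of 15 were lower (−0.34, percentile 0.06), among them Lag3 at 1.15 and 0.609 (0.606, 0.469 to 0.78) and Klrc1 at 2.66 and 1.77 (0.657, 0.548 to 0.785). Of the genes of the ILC1-like and TGF-beta response list, 11 of 15 were lower (−0.28, percentile 0.55), with Itga1 at 0.673 and 0.354 (0.455, 0.31 to 0.656). Of the maturation genes 11 of 17 were higher (0.10, percentile 95.3), with Eomes at 1.34 and 1.75 (1.36, 1.1 to 1.69). Klrg1 and Il7r were lower, Il7r at 0.37 and 0.0793 (0.277, 0.117 to 0.584).

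Among all genes found in at least 10% of NK cells, the 12 lowest in S303/7A were Ppp1r3b, Lgals7, AC163354.1, Klrb1b, Hopx, Tpm3, Ifi202b, Tmem176a, Klri2, Podnl1, Ifitm2 and Crabp1. Ppp1r3b, a glycogen-targeting subunit of protein phosphatase 1, was at 1.18 and 0.272 CP10K, a log2 ratio of −1.79. Klrb1b, an inhibitory lectin-like receptor, was at 4.13 and 1.35 (−1.54) and the cofactor gene Hopx at 3.01 and 0.973 (−1.54). The 12 highest were Tpm3-rs7, Apoe, Sik3, Nipsnap2, Pf4, Cap1, Mri1, Tmem161a, Gatm, Lyz2, Rbmxl1 and Mcm2. Of these, Apoe, Pf4 and Lyz2 are abundant in macrophages. Apoe was at 1.08 and 5.20 CP10K in NK cells, Lyz2 at 1.27 and 2.82, and the macrophage markers had a median log2 ratio of 0.82 in NK cells (7 of 8 higher).

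Without NK cells that held any UMI of 9 marker genes of other cell types, 115 WT and 14 S303/7A cells were left. In them Podnl1, Mri1, Tmem161a and Gatm were on the other side of 0 and the inhibitory receptor median was 0.10. In thinned cells Tmem161a had a log2 ratio of −0.05.

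**Figure D2:**
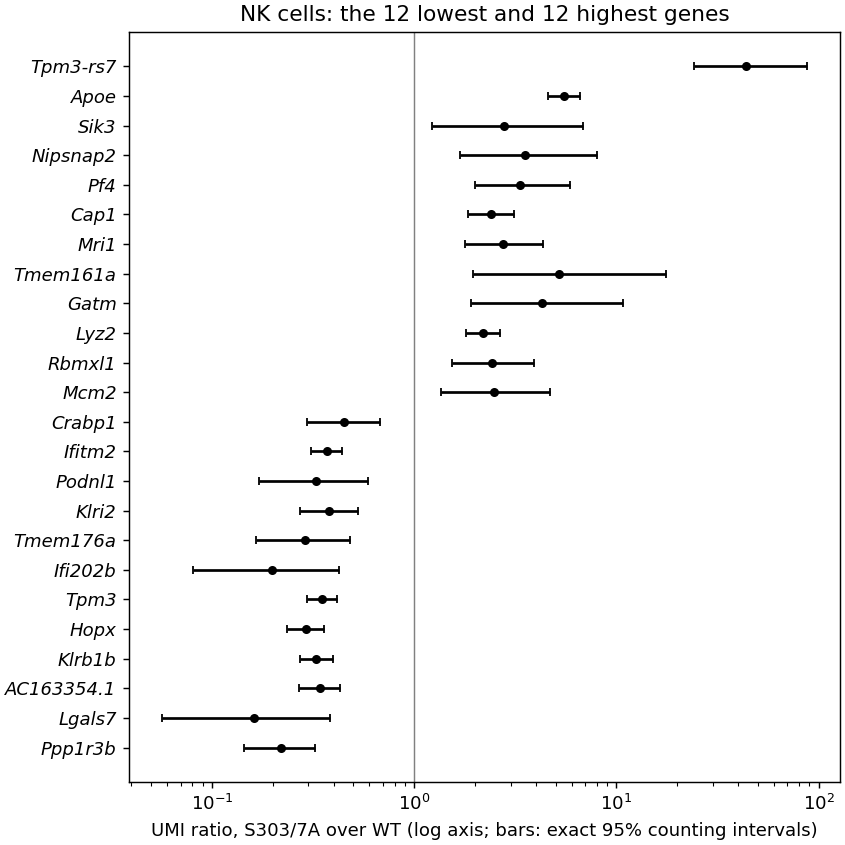
UMI ratio of S303/7A over WT (log axis) in NK cells for the 12 lowest and 12 highest genes by log2 ratio of mean CP10K, with exact 95% counting intervals. Tpm3-rs7 lay at 43.5 and Ppp1r3b at 0.22.

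Tpm3-rs7, an intron-less copy of the tropomyosin gene Tpm3, had the highest log2 ratio in each of the 6 immune classes compared among genes found in at least 10% of cells, and Tpm3 was lower in all of them. Among less often found genes, the hemoglobin gene Hbb-bs had a higher log2 ratio in CD8T, at 0.0145 and 2.66 CP10K and in 1.01% and 5.02% of cells, and in MF, at 0.0277 and 2.01. In NK cells Tpm3-rs7 (chromosome 14, 113314608 to 113316754) was at 0.0885 CP10K in WT and 3.62 in S303/7A, a UMI ratio of 43.5 (24.1 to 87.9), and Tpm3 (chromosome 3, 90072649 to 90100902) was at 4.30 and 1.56 (0.35, 0.296 to 0.413). The sum of both was 4.39 and 5.18 CP10K, a log2 ratio of 0.23, and over the 6 immune classes the sum differed by 0.01 to 0.26. In tumor cells Tpm3-rs7 stayed at 0.037 and 0.0771 CP10K. Values of each copy are uncertain, since 78.6% of the 31-base words of the 2147-base Tpm3-rs7 transcript also occur in Tpm3 transcripts, and 61.9% in its last 500 bases, the end that these libraries favor. Cap1, Mri1 and Gadd45gip1 were likewise higher in the 6 immune classes. Cap1 was at 0.66 and 1.67 CP10K in NK cells and 0.18 and 0.179 in tumor cells. Mri1 and Gadd45gip1 had log2 ratios of 1.21 and 0.90 in NK cells, and −0.10 and −0.15 in tumor cells. Both lie on chromosome 8, with starts at 84249906 and 84831522.

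**Figure D3:**
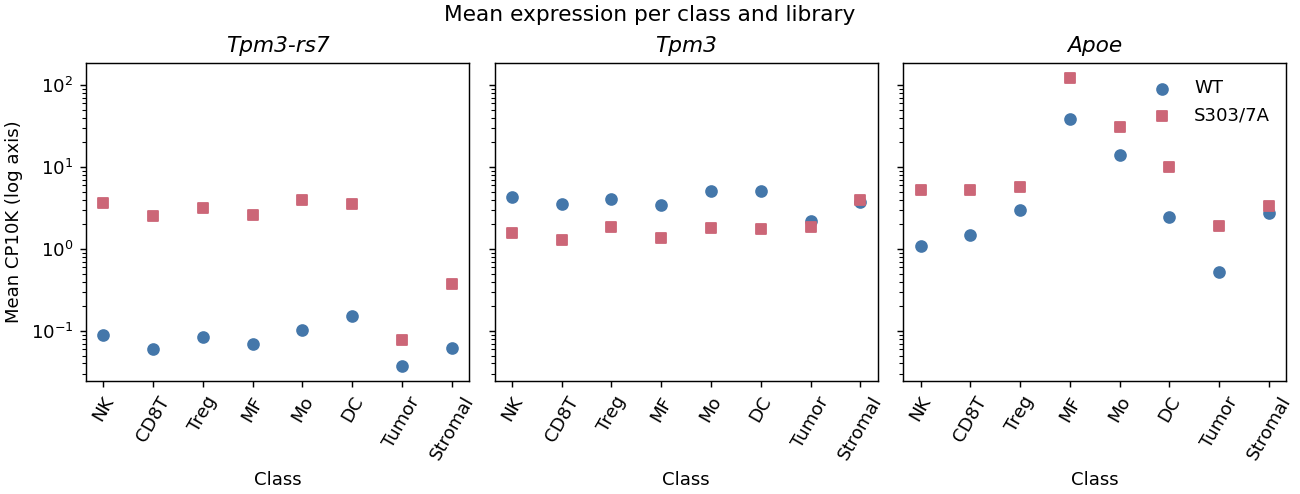
Mean CP10K (log axis) of Tpm3-rs7, Tpm3 and Apoe in each class for WT (blue circles) and S303/7A (red squares). Tpm3-rs7 was at 0.0885 in WT and 3.62 in S303/7A NK cells and at 0.037 and 0.0771 in tumor cells.

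In CD8 T cells of the S303/7A library, several effector genes and cell cycle genes took a smaller share of UMIs. Gzma was at 3.62 and 0.576 CP10K, a UMI ratio of 0.154 (0.135 to 0.175), and was found in 13.4% and 4.21% of cells. Ifng, the type II interferon, was at 5.68 and 1.96 (0.435, 0.405 to 0.468), and Gzmb at 13.3 and 6.60 (0.499, 0.48 to 0.519). Of the T cell effector genes 10 of 14 were lower, at a median of −0.34 and percentile 0, while the NK cytotoxic effector genes were at 0.10 (11 of 21 higher, percentile 98.7), with Gzmf higher at 0.626 and 1.46 CP10K. Of the proliferation genes 20 of 20 were lower (−0.58, percentile 0), with Ube2c at 2.91 and 1.38 CP10K and Birc5 at 2.58 and 1.29, and the median was −0.19 with the clusters C06 and C11 weighted equally. The other lowest genes were Tcrg-C2, Lxn and the chemokine receptor gene Ccr2, at 0.664 and 0.165 CP10K. The highest after Tpm3-rs7 were Penk, a precursor of opioid peptides, at 0.15 and 0.899 CP10K (6.11, 4.72 to 8.02), Apoe, the decoy receptor gene Il1r2 at 0.0945 and 0.453, and Cd70 at 0.0324 and 0.259. Exhaustion genes showed no common direction, 8 of 14 higher at a median of 0.05, and macrophage markers had a median of 0.74 in these cells. Hypoxia and glycolysis genes were higher in 16 of 18 cases (0.17, percentile 99.9), with Eno1 at 4.92 and 6.64 CP10K.

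In Treg of the S303/7A library, Il2ra, Tnfrsf4, Hopx and Klrk1 took a smaller share of UMIs. Il2ra, the high-affinity IL-2 receptor chain, was at 3.72 and 1.83 CP10K (UMI ratio 0.44, 0.361 to 0.535) and Tnfrsf4, which encodes OX40, at 28.4 and 18.1 (0.514, 0.479 to 0.552). The regulatory T cell program as a whole had 10 of 15 genes lower, at −0.10 and percentile 17.0. The lowest genes were Rln3, Hopx at 2.72 and 0.766 CP10K (0.261, 0.199 to 0.34), Klrk1 at 2.28 and 0.643 (0.32, 0.225 to 0.452), Cd96 and Lxn. The highest were Tpm3-rs7, Cap1 at 0.477 and 1.84 (3.46, 2.36 to 5.21), Coq8b, Gt(ROSA)26Sor at 0.441 and 1.41 (4.30, 2.74 to 7.06) and Rhod. Lists of other lymphocytes were lower too, T cell effector at −0.58 (12 of 15 lower, percentile 0) and NK activating receptor at −0.39 (11 of 16, percentile 0.79). Of the clusters made here, 1 of 153 cells was named CD8T by its markers while 60.1% of it was deposited as Treg, so other T cells within the class are not ruled out. Macrophage markers had a median of 0.40 in Treg.

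In macrophages of the S303/7A library, interferon-response, MHC class I and inflammatory genes took a smaller share of UMIs. Genes of alternatively activated and tissue macrophages took a larger one. Median depth was 2.61 times that of WT, so a smaller share need not mean fewer UMIs per cell. All 30 measured interferon response genes were lower, at a median of −0.81 and percentile 0, with Isg15 at 13.4 and 5.61 CP10K (UMI ratio 0.446, 0.436 to 0.456) and Gbp2 at 3.38 and 1.17 (0.371, 0.354 to 0.389). All 17 MHC class I presentation genes were lower (−0.57, percentile 0), while class II genes went both ways (−0.03, 6 of 10 lower, percentile 28.3), from −0.44 in C09 to 0.46 in C13. The 9 measured pro-inflammatory genes were lower (−0.68, percentile 0), with the chemokines Ccl5 at 17.6 and 7.08 (0.437, 0.429 to 0.446) and Cxcl9 at 6.71 and 3.88 (0.589, 0.572 to 0.606). That median was −0.43 with clusters weighted equally, and 0.06 in the cycling cluster C13 (5 of 9 higher, percentile 69.0). Ccl5 is also a lymphocyte gene, at 48.0 and 28.7 CP10K in CD8T, and NK cytotoxic effector genes were lower in MF as well (−0.40, 12 of 15). Of the alternatively activated genes 9 of 14 were higher (0.41, percentile 100), among them Mgl2 at 0.35 and 1.36 (3.65, 3.32 to 4.02) and Folr2 at 0.45 and 1.20 (2.57, 2.36 to 2.82). The median was 0.24 without the 2 most changed members and 0.14 in C02 (percentile 94.4). The 5 lowest genes were Ly6i, Ly6c2, Ppfia4, Plac8 and Ifi202b, and Ly6c2, a marker of inflammatory monocytes, was at 12.6 and 2.18 CP10K (0.185, 0.179 to 0.191). Hpgd, which degrades prostaglandins, was at 0.00615 and 0.244, Cbr2 at 0.53 and 1.73, and Apoe at 38.8 and 123 (2.98, 2.95 to 3.00). Ly6i and Ly6c2 lie 1.5 and 1.37 Mb from Hsf1. MF is a mix of clusters whose shares differed between libraries, and in each of C02, C03, C05, C09 and C13 the interferon median was below 0, from −1.05 in C02 to −0.45 in C13.

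Monocytes, all in cluster C07, showed lower interferon-response RNA beside higher class II RNA. All 30 interferon response genes were lower (−0.58, percentile 0), Gbp2 at 11.9 and 3.75 CP10K (UMI ratio 0.318, 0.295 to 0.342), while all 10 MHC class II genes were higher (0.58, percentile 100), H2-Ab1 at 44.2 and 76.6 (1.87, 1.83 to 1.91). The lowest genes were Ppfia4, Hopx, Hspa1a, Ccl4 at 8.31 and 2.54 (0.302, 0.276 to 0.33) and Gbp2. The highest were Tpm3-rs7, Mgl2 at 0.0171 and 0.844 (36.2, 18.2 to 84.6), the glutathione reductase gene Gsr at 0.464 and 2.44 (4.28, 3.48 to 5.31), Tmem119 and Cx3cr1. Mgl2, Tmem119 and Cx3cr1 are known from resident macrophages. Macrophage markers had a median of 0.76 in Mo (8 of 10 higher, percentile 100), with C1qa at 7.29 and 18.4 CP10K and Apoe at 13.9 and 30.3. Alternatively activated genes had a median of 0.50, which was −0.02 in thinned cells, and 30 of 30 ribosomal protein genes were higher (0.43, percentile 100).

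DC of the S303/7A library also had a smaller share of interferon-response RNA, with all 30 genes lower (−0.85, percentile 0). Isg15 was at 16.7 and 6.68 CP10K (UMI ratio 0.40, 0.377 to 0.424). All 17 class I genes were lower too (−0.41, percentile 0). Proliferation genes were higher in 19 of 20 cases (0.44, percentile 100), with Stmn1 at 1.41 and 2.45 (1.60, 1.43 to 1.80). The lowest genes were Timd4, a receptor for phosphatidylserine, at 1.02 and 0.0536 (0.0485, 0.0271 to 0.0811), Hspa1a, Plac8, Ly6c2 and Ifitm6. The highest were Tpm3-rs7, Apoe, Pf4, Ccl8 and Cx3cr1, which with Apoe at 2.46 and 9.87 go with a median of 1.00 for macrophage markers in DC. The 3 DC clusters held similar shares of the class in both libraries, C16 at 47.8% and 49.4%.

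Tumor cells are compared by cluster, because C01 was led by fibroblast markers (Col1a1, Col3a1 and Lum). No tumor marker of the fixed lists was among the leading genes of any of the clusters. These lists cover melanoma and carcinoma only, so that absence does not bear on whether the cells are tumor cells. In C01, C04 and C08, interferon-response and MHC class I RNA was lower in S303/7A, and in C14 interferon-response RNA was higher. The interferon response medians were −1.05 in C01 (29 of 29 genes lower), −1.01 in C04 (27 of 27), −0.50 in C08 (24 of 25) and 0.51 in C14 (20 of 25 higher), at percentiles 0, 0, 0 and 100. The chemokine gene Cxcl10 was at 4.00 and 0.705 CP10K in C01 and at 1.37 and 2.24 in C14, and Isg15 at 7.93 and 2.43 in C01 and 1.78 and 2.98 in C14. MHC class I presentation medians were −0.72, −0.69, −0.47 and −0.27 in the same order. MHC class II medians were higher in C04 (1.33, 7 of 7 genes), C08 (0.48, 6 of 6) and C14 (0.28, 5 of 5), and −0.16 in C01. Class II genes are abundant in macrophages, and macrophage markers were higher in the same clusters (0.87 in C04, 0.67 in C08, 1.00 in C14). They were higher in C01 as well (0.64, 4 of 4 genes), where 4 of 6 class II genes were lower. Macrophage markers and class II genes thus did not rise together in every cluster. Heat shock response medians were −0.23, −0.24, −0.25 and −0.04, with Hsp90aa1 at 3.43 and 2.24 CP10K over the whole class. C14 was led by Trib3 and Ddit3, genes of the integrated stress response, beside Mmp3 and Ereg.

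Over the whole Tumor class the 5 lowest genes were Cxcl10, Isg15, Pclaf, Hist1h2ap and Ube2c and the 5 highest Lcn2, Apoe, Mt1, Id2 and Ptgs2. Pclaf, Hist1h2ap and Ube2c are cell cycle genes, and C04 took a smaller share of S303/7A tumor cells. Within clusters the proliferation medians were nearer 0 in C01 (−0.12, percentile 0.85), C04 (−0.10, 15 of 20 lower, percentile 7.59) and C08 (−0.17, percentile 2.76), and −0.53 in C14 (7 of 9 lower, percentile 0), against −0.64 over the whole class. Lcn2, an iron-sequestering secreted protein, was at 0.19 and 3.64 CP10K in C14 and at 0.0142 and 0.0711 in C01. Mt1, a metal-binding metallothionein, was higher in S303/7A in each of these clusters, from 4.25 and 8.06 in C01 to 18.7 and 44.7 in C08, as was Id2, from 0.396 and 0.715 in C04 to 0.452 and 1.54 in C08.

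The Stromal class, cluster C15, had a smaller share of interferon-response RNA in S303/7A. The class is mixed: 66.9% of its WT and 56.5% of its S303/7A cells lay in copy number groups 2 and 3, as most tumor cells did. The values here are not split by these groups. Macrophage markers were lower in 8 of 9 cases (−0.45, percentile 5.3), and pro-inflammatory genes in 6 of 8 (−0.78, percentile 1.75). The interferon response median was −0.78 (24 of 28 lower, percentile 0), with Cxcl10 at 1.21 and 0.02 CP10K (UMI ratio 0.0239, 0.00768 to 0.0566). Ccl2, a monocyte attractant, was at 1.90 and 0.147 (0.0522, 0.0334 to 0.078), found in 15.3% and 13% of cells, so its mean rests on high counts in few WT cells. Csf1, the macrophage growth factor, was at 0.643 and 0.0489 (0.083, 0.0295 to 0.189), followed by AI413582, Cxxc5 and Bdnf. Igfbp3 was at 0.773 and 3.20 (7.67, 6.29 to 9.44), and of the other 4 highest genes Chmp1b, Trappc13 and Pglyrp1 had counting intervals that included 1 and Eipr1 was at 2.94 (1.11 to 9.10). Matrix genes were lower in 9 of 13 cases (−0.24, percentile 6.03), with Col1a2 at 3.95 and 1.19 CP10K.

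Set side by side over the classes, interferon response genes were lower in S303/7A myeloid cells, Stromal cells and 3 of the 4 tumor clusters, and lower by less in NK cells (−0.15, 26 of 30 lower, percentile 2.07) and CD8T (−0.13, 17 of 30, percentile 1.02). In Treg the median was −0.02 (percentile 59.7), and −0.17 with summed UMIs. Ly6a, which lies 1.48 Mb from Hsf1, was among the lower members in NK cells, at 8.24 and 5.15 CP10K. MHC class I presentation stood at 0.03 in NK cells (percentile 74.4), −0.13 in CD8T and −0.12 in Treg, against −0.38 in Mo and −0.43 in Stromal cells. Unfolded protein response genes had medians of −0.19 in NK cells, −0.21 in CD8T, −0.28 in Treg, −0.12 in MF, −0.26 in Mo and 0.02 in DC. The median log2 ratio of all detected genes lay between −0.07 in Stromal cells and 0.07 in Mo, so these values hardly depend on centring.

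**Figure D4:**
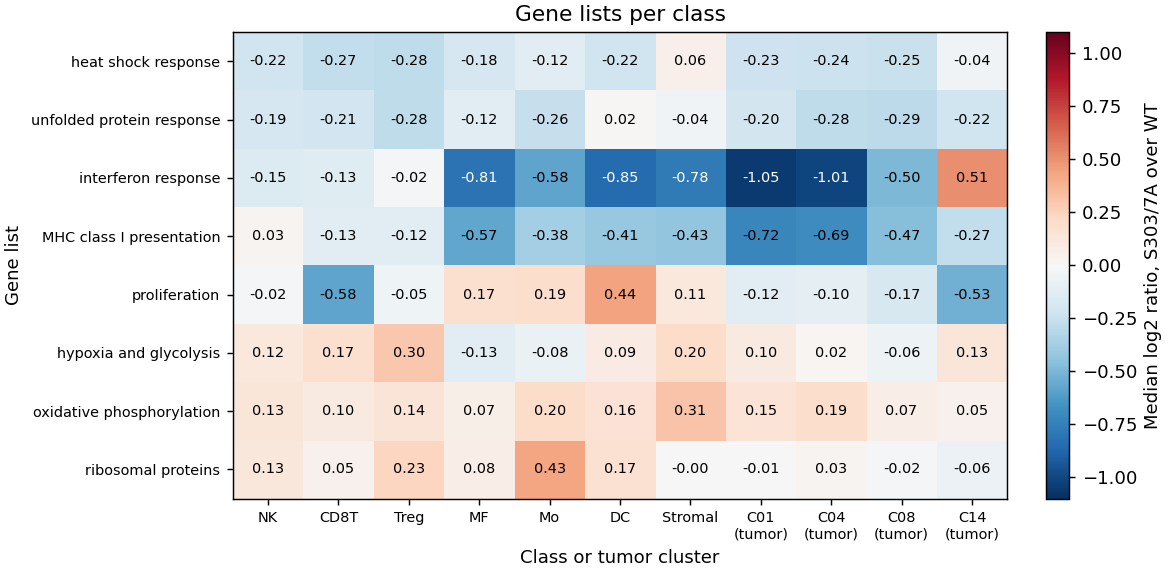
Median log2 ratio (S303/7A over WT; color and printed value) of 8 gene lists in 7 classes and the 4 tumor clusters. Interferon response was −0.81 in MF and −1.05 in C01, and 0.51 in C14.

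Gr, plasmacytoid DC and B cells had fewer than 50 cells in at least 1 library, and their expression was not compared.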

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

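In this part the test of free macrophage RNA in tumor cells was chosen only after the result was seen, and those of cluster mix and depth were written before their values were computed. Results were set apart here when a gene list stood below nearly all random lists in 1 class and above nearly all in another, or when a signal appeared in data outside the comparisons. The differences between classes were not tested.

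Interferon response genes had a median log2 ratio of 0.51 in tumor cluster C14, opposite to −1.05 in C01. Immune evasion genes of tumors had 0.45 in C14 and −0.28 in C01. Proliferation genes had 0.44 in DC and −0.58 in CD8T. Chemokine genes for lymphocytes and DC had 0.39 in DC and −0.42 in Mo, hypoxia and glycolysis genes 0.30 in Treg and −0.13 in MF, and oxidative stress genes 0.28 in C14 and −0.30 in Mo. The copy number groups, which no comparison used, placed 66.9% (59.1 to 74.0) of WT and 56.5% (47.8 to 64.9) of S303/7A Stromal cells in groups 2 and 3, where 94.3% and 95.1% of tumor cells lie, against 2.37% and 0.913% of macrophages.

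The lower interferon response of S303/7A macrophages and tumor cells was weighed against technical causes. A different mix of clusters does not account for it, since 8 of the 9 macrophage and tumor clusters had a median below the 2.5% point of random lists. Macrophages thinned to 1000 UMIs had a median of −0.71, against −0.81 before. Thinning keeps each gene's expected share of a cell's UMIs, so this test could not decide whether depth plays a part. Less free macrophage RNA in S303/7A tumor cells is argued against by macrophage markers, which were higher there (0.69). These markers do not measure the interferon response RNA within free RNA. Since that RNA was lower in S303/7A macrophages themselves (−0.81), a part of the tumor cell difference from free RNA is not excluded. The genotype, other differences between the mouse lines, the pools of mice, depth and the day of preparation may each remain behind the difference. With 1 library per genotype they cannot be separated.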

How the results depend on the processing

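Of the leading list medians, 247 values under alternatives stayed within the spread of random lists around the main value, 50 moved and 1 reversed. Of the other list medians the counts were 928, 79 and 9. Named genes and shares were judged by their counting intervals instead, with counts of 431, 192 and 5 for genes and 38, 13 and 0 for shares. With other detection filters (none, or 25% of cells), the sets of named genes counted as the same in 8 checks and as moved in 8. Which medians lead, and which pairs of list and class were run, was settled after a first run had been seen, so these counts depend on that choice. Thinning of lists, equal cluster weights, lists without doublets and shares without C09 were also added after the data were seen. The cause was not tested for any of the values below, except that a larger pseudocount shrinks, and a smaller one widens, every ratio by construction.

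With a pseudocount of 1 the heat shock medians were −0.0812 in NK, −0.10 in CD8T, −0.0760 in MF, −0.11 in C01, −0.13 in C04 and −0.12 in C08. Interferon response was then −0.43 in MF, −0.48 in DC, −0.25 in Stromal, −0.48 in C01, −0.35 in C04, −0.14 in C08 and 0.16 in C14, and MHC class I −0.42 in MF, −0.45 in C01, −0.42 in C04, −0.27 in C08 and −0.10 in C14. Inhibitory receptors were −0.13 in NK, T cell effector −0.18 and proliferation −0.28 in CD8T, and pro-inflammatory −0.23 and alternatively activated 0.23 in MF. With 0.01, inhibitory receptors were −0.59 in NK, interferon response −1.08 in Stromal, −1.28 in C01, −1.23 in C04, −0.59 in C08 and 0.66 in C14, and MHC class I −0.84 in C01 and −0.90 in C04.

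With summed UMIs, interferon response was −0.17 in Treg, −0.71 in MF and −0.85 in C04, MHC class I −0.11 in C14, and in Stromal hypoxia and glycolysis was −0.0298 and mitochondrially encoded genes 0.0418, both reversed. In thinned cells interferon response was −0.71 in MF, −1.13 in C01 and 0.81 in C14, MHC class I −0.70 in Stromal, −0.89 in C01 and −0.89 in C04, and heat shock −0.36 in Mo; alternatively activated genes in Mo (−0.0190), proliferation in C01 (0.12), the unfolded protein response in C14 (0.00524) and Tmem161a in NK (−0.0468) reversed. Without doublets interferon response was −1.15 in C01, −1.16 in C04 and −0.41 in C08, and MHC class I −0.85 in C04.

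With clusters weighted equally, proliferation was −0.19 in CD8T and pro-inflammatory −0.43 in MF, and in MF immediate early (0.0211) and proliferation (−0.0261) reversed. Without the 2 most changed members, alternatively activated was 0.24 in MF, and chemokines in MF (0.20) and oxidative stress in C08 (−0.0108) reversed. In NK cells without markers of other types (14 left in S303/7A), MHC class I was 0.36, and inhibitory receptors (0.10), Podnl1 (0.27), Mri1 (−0.0457), Tmem161a (−0.40) and Gatm (−0.47) reversed.

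With all cells as denominator the share ratios were 1.23 in CD8T, 1.47 in DC, 1.45 in MF, 0.713 in Mo, 0.753 in NK, 1.17 in Stromal, 1.20 in Treg and 0.556 in Tumor; the mix of sorted cells enters these by construction. Clusters made here gave 1.87 in MF and 0.171 in Mo, and leaving out C09 1.26 in MF. Without the shallowest 10% of cells the share ratio was 0 in B and 1.20 in Stromal, and the ratio of median UMIs 1.35 in Gr and 1.57 in Stromal; it gave no value in B, where no S303/7A cell was left. Leaving out a replicate was not possible with 1 library per genotype.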

Other observations

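In this part the tests of the summed Tpm3 copies, of macrophage marker UMIs and of the Apoe share were chosen only after the results were seen, and the others were written before their values were computed.

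Oxidative phosphorylation genes had medians above 0 in each class, from 0.31 in Stromal cells and 0.13 in NK cells (20 of 25 higher, percentile 99.8) to 0.07 in MF, which lay within the range of random lists (percentile 90.7). Ribosomal protein genes were higher in NK cells (22 of 30, 0.13) and Treg (28 of 30, 0.23). Proteasome genes were lower in 23 of 25 cases in C01 (−0.14, percentile 0.05) and even in NK cells (0.02). Apoptosis genes had a median of −0.16 in NK cells and mitochondrially encoded genes 0.01.

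Crabp1, abundant in tumor cells at 25.7 CP10K in WT and 19.4 in S303/7A, was at 0.693 and 0.257 in NK cells and 1.11 and 0.413 in MF, so the low level in immune cells was lower in the library with fewer CD45-negative cells. In the same NK cells the macrophage gene Apoe was higher in S303/7A, the library with the larger macrophage share.

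Tpm3-rs7 was higher and Tpm3 lower in the immune classes of S303/7A. Reads moving between these copies, which share 61.9% of 31-base words in the last 500 bases, may account for it: their sum differed by at most 0.26 on the log2 scale in the 6 immune classes. A chromosome segment around Hsf1 that differs between the mice is argued against for these genes, which lie on chromosomes 14 and 3. Of 8 genes shifted alike in all 6 immune classes, 1 (Ly6c2) lay within 10 Mb of Hsf1. That was no more than the upper limit of random draws (1), though above their mean of 0.145. With 8 such genes the count cannot decide whether such a segment shifts other genes. Mri1 and Gadd45gip1, also among the 8, lie near each other on chromosome 8, and only the region around Hsf1 was tested. A sequence difference between the mouse lines at Tpm3 or elsewhere in the genome, and the genotype itself, remain open and untested.

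Macrophage genes were higher in S303/7A lymphocytes and tumor cells. Free RNA from macrophages is a candidate source. UMIs of the 10 macrophage markers per cell were 2.52 times as many in S303/7A tumor cells and 4.31 times in NK cells. As a share of UMIs, which scales by depth, they were 0.0345% against 0.0150% in tumor cells and 0.129% against 0.0484% in NK cells. In the Stromal class, however, 8 of 9 measured markers were lower (median −0.45, percentile 5.3 of random lists). Free RNA reaching every class alike would raise them there too, and no rise was seen. That median lay within the range of random lists (−0.57 to 0.38), and marker UMIs per cell were not counted in this class. The Stromal values therefore do not decide on free RNA. In thinned cells Apoe was found in 31.1%, 31.4% and 31.6% of S303/7A NK, CD8T and Treg cells, against 8.24%, 10.7% and 13.1% in WT (unthinned NK 77.8% and 27.2%, at median depths of 5864.5 and 3621 UMIs). Doublets with macrophages are argued against by the difference in NK cells of 22.8 percentage points, beyond 3 times the expected doublet rate of 3.84%. In thinned NK cells the median of the markers was 0.74, against 0.82 unthinned. Thinning keeps each gene's expected share of a cell's UMIs, so this test could not decide on depth. Uptake of macrophage material by these cells was not tested.

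Part of the Stromal class may be grafted cells. In S303/7A, Tpm3-rs7, high in immune and low in tumor cells there, had a mean of 0.179 CP10K in 78 Stromal cells of copy number groups 2 and 3 and 0.624 in 60 cells of group 1, short of the 5 times set for the test on this mean. Summed UMIs gave a wider contrast, 0.141 per 10000 (0.0703 to 0.252; 11 UMIs) against 1.70 (1.30 to 2.17; 62 UMIs), past 5 times. Since the 2 measures differ and the test was set on the mean, the question stays open. Krt8 and Krt18 had 0 UMIs in the cells of groups 2 and 3, and 47 and 51 in those of group 1.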
